A study of Sus scrofa with 3 samples.

How the data were processed

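RNA was measured in 3 libraries of SSEA4-positive spermatogonia from pigs aged 90 days. SSEA4, stage-specific embryonic antigen 4, is a glycolipid of the cell surface. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries, which were read as 150 bp pairs on an Illumina HiSeq 4000. Per the same protocols, reads were trimmed with cutadapt 1.9.3, aligned with HISAT2 2.0.4 and summarised per Ensembl gene by Cuffdiff, part of Cufflinks. The protocols name susScr3 as the genome, and the submitters' processing notes name both susScr3 and Sscrofa11.1, so no coordinates are given.

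The values deposited by the authors are FPKM (fragments per kilobase of gene and 1000000 mapped fragments), per the labels' protocols. The name of the deposited table says TPM instead. The 3 columns sum to 859642, 855276 and 781871, which is less than 1000000 and differs between libraries. Neither unit is excluded by these sums, since rows may have been left out of a TPM table. Within a library the 2 units differ by a single factor, so ratios of values between genes are not touched by the doubt. The level of 1 FPKM and ratios between libraries are touched by it. So are differences between genes or lists in log2(FPKM + 1), because 1 is added to each value. Results were therefore also computed after rescaling each library to 1000000, an alternative chosen after the data were seen.

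The depth of the libraries is unknown, because the table holds no counts. Among 1429 genes under 0.15 FPKM and above 0 in every library, at most 3 shared the same ratio between the libraries S1 and S2 (to 4 decimals), so whole reads could not be recovered from steps in the low values. No counting interval or detection floor is given for this reason. A value of 0 in such a table can also be a failed estimate.

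The columns are named S1, S2 and S3, and these names do not tell which of the 3 labelled samples each column is, so they are used as libraries of 1 group. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The study's design also names undifferentiated spermatogonia as a second population. Libraries of that population were not analysed here, so no difference between populations could be tested. 

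The table had 18730 rows, each an Ensembl gene. Symbols came from the table for 14623 rows and, where it gave none, from a reference table of Ensembl names for 737 rows, while 3370 rows stayed without a symbol. The reference table matched 14749 IDs. The 2 sources gave different symbols for 334 rows, which were not used as list members unless the reference symbol was the list gene. In 170 genes a value under 1e-06, taken as numerical underflow, was set to 0; this limit and the exclusion of rows with differing symbols were chosen after the values were seen. After this, 781 genes were at 0 in all libraries and 17949 were tested.

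Values were tested as log2(FPKM + 1), with a pseudocount of 1. The limma test of the mean against the level of 1 FPKM used an intercept only, eBayes with a trend and Benjamini-Hochberg adjustment over 17949 genes, two-sided, with a threshold of 0.05. Differences on this scale understate the change of low genes. In simulated data the test called 4.45% of 2000 genes placed exactly on the level, 83.5% of 200 genes at 1.5 times the level, 100% of 200 at 2.0 times and 98.5% of 200 at 0.5 times.

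Before the data were examined, 24 gene lists, 14 pairs of lists, the test, the alternatives and the rule for naming genes were fixed. The lists held 414 different genes, of which 359 were measured here. The level of a list is the median of log2(FPKM + 1) over its members in each library, and it was set against 10000 random lists of the same size from the 17949 genes, as a description. In simulated data, 0.5% of 200 random lists of 15 genes and 100% of 200 lists from the 25% of genes with the highest levels lay in the upper 2.5% of random lists. Pairs of lists were compared by their mean log2(FPKM + 1) per library, leaving out shared members, with an exact two-sided sign-flip permutation test and Benjamini-Hochberg adjustment over the 14 pairs. With 3 libraries this test cannot give a p under 0.25. Differences between libraries were described as a list's median log2 difference of 1 library from the mean of the other 2, set against 10000 random lists drawn from the window of 201 genes nearest in expression to each member; this description was added after the data were seen.

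Genes were named by this rule: for each list, from the 4 highest and 2 lowest measured members; any member of the lists for undifferentiated and differentiating spermatogonia, globo-series synthesis and pluripotency; the 10 genes with the highest mean apart from mitochondrially encoded genes, ribosomal protein genes and rows with no symbol; and the 10 genes of at least 10 FPKM with the largest SD of log2 values. Alternatives were a pseudocount of 0.1, quantile normalization, removal of the 13 mitochondrially encoded and 62 ribosomal protein genes with the rest rescaled to 1000000, levels of 0.5 and 5 FPKM, a filter at a mean of 0.5 FPKM, no filter, eBayes without a trend, medians in place of means, and leaving out each library. The globo-series list was also compared without UGCG, B4GALT5 and B4GALT6, chosen after the values were seen. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.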

Results

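Gene expression was measured in 3 libraries, S1, S2 and S3, of porcine spermatogonia sorted for SSEA4, the globo-series glycolipid which the study examined as a marker for enriching spermatogonial stem cells. Of 18730 genes, 17440 ± 13.1 (SD, n = 3) had a value above 0 per library and 12317 ± 85.3 had 1 FPKM or more. Across 17949 genes, limma with Benjamini-Hochberg adjustment placed 11771 above 1 FPKM and 5111 below it by more than the spread between libraries, and 1067 were not told apart from it. With mitochondrially encoded and ribosomal protein genes removed and the rest rescaled, 13667 lay above and 2924 below, so the share above moved from 69.7% to 82.4% of the calls. The depth behind these values is unknown. Genes with a mean of 1 FPKM or more had a median coefficient of variation of 9.34% between libraries.

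Genes of the germ line were mostly above the level. Among 11 measured genes shared by germ cells of several stages, 10 lay above 1 FPKM, led by SYCP3, a component of the meiotic chromosome axis, at 403 ± 32.6 FPKM (SD, n = 3), STK31 at 145 ± 15.1 and DDX4, the germ cell RNA helicase, at 81.5 ± 3.18. TEX11 stood at 0.997 ± 0.147 FPKM and was not told apart from the level, but lay above it, at a log2 difference of 1.01, with mitochondrial and ribosomal protein genes removed. Of 23 genes of the piRNA pathway and DNA methylation, 22 lay above 1 FPKM, with ASZ1 at 193 ± 12.8 and GTSF1 at 124 ± 13.2, and TET1 lay below it at 0.709 ± 0.124 (limma, adjusted p = 0.00846). TET1 was not told apart from the level after each library was rescaled to 1000000, at a log2 difference of -0.11, and lay above it with mitochondrial and ribosomal protein genes removed, at 0.66. The median of the first list exceeded 99.9% of 10000 random lists of its size and that of the second exceeded 100% of them. On the same measure the undifferentiated list exceeded 97.6%, the meiotic list 96.1% and the differentiating list 94.3%. The first list stood 1.54 ± 0.04 above that of undifferentiated spermatogonia on the log2 scale (SD, n = 3), in 3 of 3 libraries.

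Of 28 measured genes of undifferentiated spermatogonia, 25 lay above 1 FPKM, 2 lay below and 1 was not told apart, and the counts adjusted over the list alone were 25 and 2. The highest were ELAVL2 at 140.1 ± 10.2 FPKM, NANOS3 at 63.9 ± 29.8, ITGA6, an integrin subunit used to enrich stem cells, at 47.9 ± 1.29, and ETV5, a transcription factor of the self-renewal response to GDNF, at 46.8 ± 7.17. UCHL1, a marker of spermatogonia in livestock, stood at 24.7 ± 1.99, ID4 at 22.7 ± 5.01 and RET, the GDNF co-receptor kinase, at 20.1 ± 3.04. ZBTB16 reached 5.16 ± 0.406, GFRA1, the GDNF receptor, 2.96 ± 0.742, and THY1 1.96 ± 0.334. BCL6B at 0.194 ± 0.0394 and LIN28A at 0.225 ± 0.0912 lay below 1 FPKM, and EOMES stood at 0.911 ± 0.0162 (limma, adjusted p = 0.207). With mitochondrial and ribosomal protein genes removed, LIN28A was not told apart from the level, at a log2 difference of -0.26, and EOMES lay above it, at 0.92. In the library S3 this list stood 0.15 higher on the log2 scale than in the other 2 libraries, above 98.2% of matched random lists. This value was 0.26 after rescaling each library to 1000000, which moved the median of all genes with a mean of at least 1 FPKM to 0.17, and relative to all such genes it was 0.09 after that rescaling. In the same library the Sertoli list stood at -0.36 and the stress and early response list at -0.35.

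**Figure D1:**
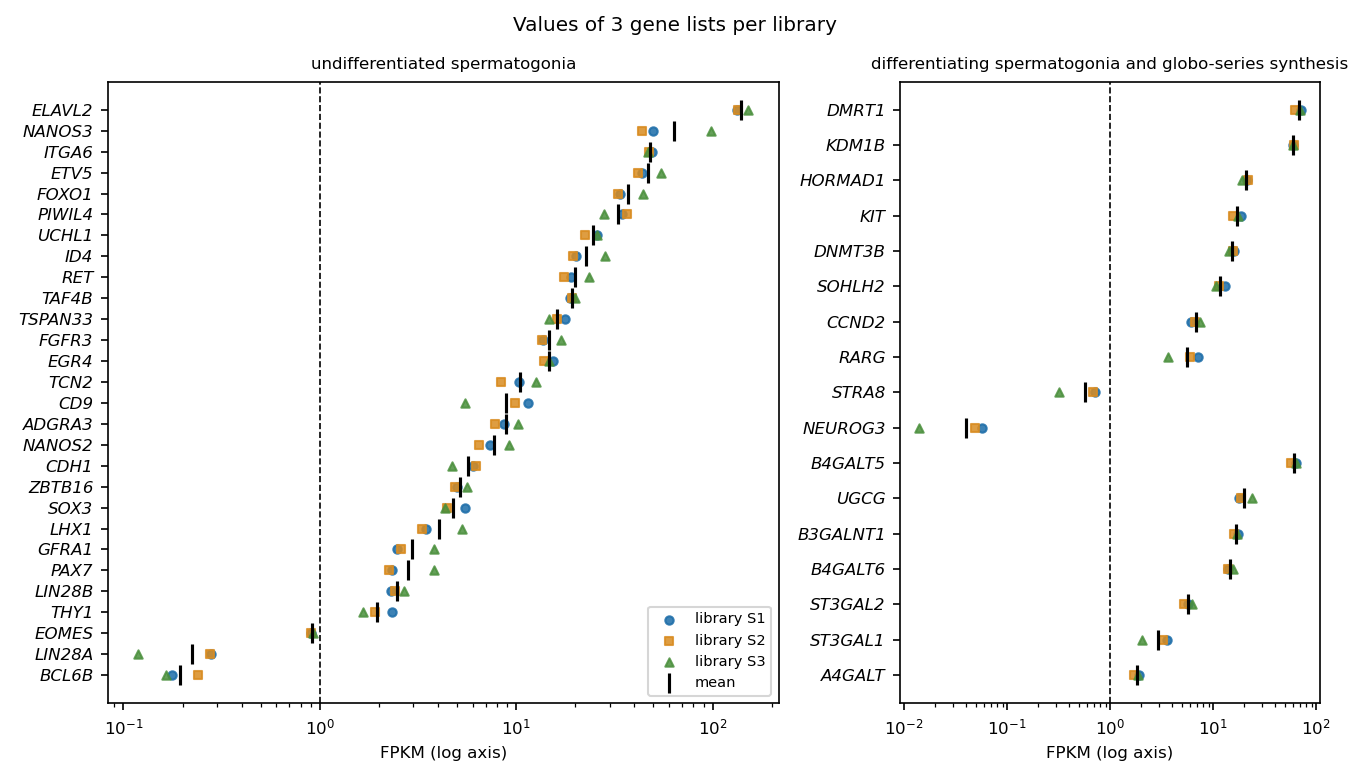
FPKM (log axis) of each measured gene of the lists for undifferentiated spermatogonia (left), differentiating spermatogonia and globo-series synthesis (right) in libraries S1, S2 and S3, with a bar at the mean and a dashed line at 1 FPKM. ELAVL2 is the highest gene at a mean of 140 FPKM, and NEUROG3 the lowest at 0.0402.

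Of 10 measured genes of differentiating spermatogonia, 8 lay above 1 FPKM, among them DMRT1 at 67.2 ± 4.40 FPKM, KDM1B at 59.5 ± 0.777 and KIT, the receptor for stem cell factor, at 17.1 ± 1.40. STRA8, the retinoic acid target of meiotic entry, lay below 1 FPKM at 0.572 ± 0.220, as did NEUROG3 at 0.0402 ± 0.0230. With mitochondrial and ribosomal protein genes removed, the log2 difference of STRA8 from the level turned from -0.36 to 0.43 and it was not told apart from the level. The mean log2 level of the undifferentiated list minus that of the differentiating list was -0.01 ± 0.16 (SD, n = 3 libraries), higher in 1 of 3 libraries (exact sign-flip permutation test, p = 1, adjusted p = 1). The difference was smaller than its spread and changed sign without S1 or without S2, at 0.03 in each case. In S3 the median difference of the differentiating list from the other 2 libraries was -0.10, with 1.63% of matched lists lower. It was -0.19 with mitochondrial and ribosomal protein genes removed and -0.04 after rescaling to 1000000. Over the 8 members with a mean of at least 1 FPKM that rescaling changed the sign, from -0.08 to 0.04. It also moved the median of all genes with such a mean to 0.17. Relative to those genes the value over all members was -0.21.

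Meiotic transcripts were also present. Of 24 measured genes, 23 lay above 1 FPKM, led by the meiotic cohesin genes SMC1B at 139 ± 25.9 FPKM and STAG3 at 104 ± 17.6, SPATA22 at 71.1 ± 10.2 and SYCP1, of the synaptonemal complex, at 63.5 ± 11.6. MEI1 lay below at 0.507 ± 0.118, but above, at a log2 difference of 0.34, with mitochondrial and ribosomal protein genes removed. The undifferentiated list minus the meiotic list was -0.27 ± 0.06 on the log2 scale, higher in 0 of 3 libraries, and had the opposite sign, 0.07, when medians replaced means. The meiotic list was 0.31 higher in S3 than in the other 2 libraries, above 100% of 10000 matched lists. Spermatid genes lay mostly under the level: 14 of 23 were below 1 FPKM and 7 above. Among the latter were ODF2 at 48.6 ± 1.72 FPKM, SPACA1 at 23.6 ± 4.63 and LDHC at 10.8 ± 0.676. The spermatid list median was 0.56 on the log2 scale, under the level at 1, and exceeded 0.17% of random lists of its size. With mitochondrial and ribosomal protein genes removed it was 1.27, over the level, and exceeded 0.23%. Under the filter at a mean of 0.5 FPKM, which leaves out low members, it was 2.11 and exceeded 7.18%. PRM1, a protamine of condensing sperm chromatin, differed between libraries, at 51 FPKM in S1, 1.53 in S2 and 11 in S3. The undifferentiated list exceeded the spermatid list by 2.08 ± 0.32 in 3 of 3 libraries. Among the 14 pairs of lists compared, each of the 13 other than undifferentiated against differentiating had the smallest two-sided p that 3 libraries allow, 0.25 (exact sign-flip permutation test, adjusted p = 0.269).

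Of 8 listed genes for enzymes that build the globo-series, to which SSEA4 belongs, 7 were measured, and B3GALT5 was not analysed here. The 7 measured genes lay above 1 FPKM: B4GALT5 at 61.3 ± 3.97, UGCG, the glucosylceramide synthase, at 20.0 ± 3.09, B3GALNT1 at 16.8 ± 0.715, B4GALT6 at 14.5 ± 0.894, ST3GAL2, a sialyltransferase able to complete SSEA4, at 5.67 ± 0.535, ST3GAL1 at 2.94 ± 0.784 and A4GALT at 1.83 ± 0.0988. Of 6 genes of the ganglio-series, 2 lay above, ST3GAL5 at 3.83 ± 0.671 and ST8SIA5 at 2.40 ± 0.349, 2 lay below and 2 were not told apart. The globo-series list exceeded the ganglio-series list by 2.33 ± 0.14 on the log2 scale in 3 of 3 libraries. UGCG and the B4GALT enzymes act before the branches part. Without these 3 genes, an alternative chosen after the values were seen, the difference was 1.40 ± 0.08 (SD, n = 3) in 3 of 3 libraries. Whether the genes left act in the globo-series alone was not examined, so this is not a contrast of 1 branch with the other. Of the 4 globo-series genes left, B3GALNT1 and ST3GAL2 stood above ST3GAL5, the highest ganglio-series gene. ST3GAL1 and A4GALT stood under it, so the difference does not hold gene by gene.

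Of 15 listed pluripotency genes 12 were measured, of which 4 lay above 1 FPKM and 6 below. POU5F1 and SOX2 were not among the 12 measured members, so the values of this list do not cover them. The list median was 0.87 on the log2 scale, under the level at 1, and exceeded 5.47% of random lists of its size. With mitochondrial and ribosomal protein genes removed it was 1.82, over the level, and exceeded 5.55%. Under the filter at a mean of 0.5 FPKM, which leaves out low members, it was 3.35 and exceeded 59.85%. The 4 genes above 1 FPKM were KLF2 at 23.9 ± 6.23 FPKM, MYC at 15.3 ± 6.02, DPPA5 at 10.8 ± 2.12 and KLF4 at 10.7 ± 2.49, transcription factors apart from DPPA5. KLF2, MYC and KLF4 were lowest in S3, at 18.1, 8.70 and 8.37 FPKM, whereas DPPA5 was highest there, at 13.2. NANOG stood at 0.145 ± 0.0949 and TDGF1 at 0.0325 ± 0.0321. The undifferentiated list exceeded the pluripotency list by 1.81 ± 0.16 in 3 of 3 libraries.

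Markers of other cells of the testis were detected at lower list levels, with single genes high. The lists hold different genes and no other cells were analysed here, so these levels do not measure the share of each cell type. Of 18 Sertoli cell genes, 12 lay above 1 FPKM, including BEX1 at 263 ± 12.7 FPKM, CLU at 228 ± 100.1, VIM at 102 ± 32.9 and WT1 at 42.8 ± 2.5, and 6 lay below, including GATA1 at 0.0339 ± 0.0136 and DHH at 0.0203 ± 0.0205. Of 12 Leydig cell genes, 7 lay above, with CYP11A1, the first enzyme of steroid synthesis, at 8.13 ± 4.89, and 4 below, with STAR at 0.0768 ± 0.0305. Of 16 peritubular and fibroblast genes, 13 lay above, with DCN at 31.4 ± 3.20 and TAGLN at 23.5 ± 14.2. Of 10 endothelial genes, 4 lay above, with ERG at 8.20 ± 1.0. Among 18 leukocyte genes only CD74, at 17.0 ± 2.25, lay above and 11 lay below. Among 5 erythroid genes only HBB, at 3.38 ± 0.532, lay above. The list medians exceeded 46.15% of random lists of the same size for peritubular, 28.67% for Sertoli, 20.58% for Leydig and 12.12% for endothelial genes. The undifferentiated list exceeded the Sertoli list by 0.71 ± 0.32, the peritubular list by 1.14 ± 0.23, the Leydig list by 1.97 ± 0.30, the endothelial list by 2.01 ± 0.20, the leukocyte list by 2.71 ± 0.10 and the erythroid list by 2.74 ± 0.09, each in 3 of 3 libraries. The median difference of S3 from the other 2 libraries was -0.36 for the Sertoli list, with 0% of 10000 matched lists lower, -0.20 for the endothelial list, with 0.98% lower, and -0.12 for the peritubular list, with 1.62% lower. It lay within the central 95% of matched lists for the Leydig list, at -0.11 with 4.98% lower, the leukocyte list, at -0.0042 with 58.1% lower, and the erythroid list, at 0.015 with 63.5% lower. Among members with a mean of at least 1 FPKM only, the median in S3 was -0.54 for 8 Leydig, -0.49 for 12 Sertoli, -0.23 for 6 endothelial and -0.11 for 13 peritubular genes. Minus the median of all genes with such a mean, it was -0.60 for Leydig genes, with a 95% bootstrap interval over genes from -0.96 to -0.13. It was -0.54 (-1.03 to -0.13) for Sertoli, -0.28 (-0.44 to -0.02) for endothelial and -0.16 (-0.42 to -0.10) for peritubular genes. After rescaling to 1000000 the values over all members were -0.29 for Sertoli, -0.13 for endothelial, -0.05 for peritubular and -0.06 for Leydig genes. That rescaling moved the median of all genes with a mean of at least 1 FPKM to 0.17, and relative to it the values were -0.46, -0.30, -0.22 and -0.23. With mitochondrial and ribosomal protein genes removed the values were -0.53, -0.34, -0.24 and -0.21. The leukocyte value over all its members changed sign under quantile normalization and after rescaling to 1000000. After that rescaling it was 0.02, or -0.15 relative to all genes. Over its 4 members with a mean of at least 1 FPKM, at 0.08 as deposited, it kept its sign in both settings.

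**Figure D2:**
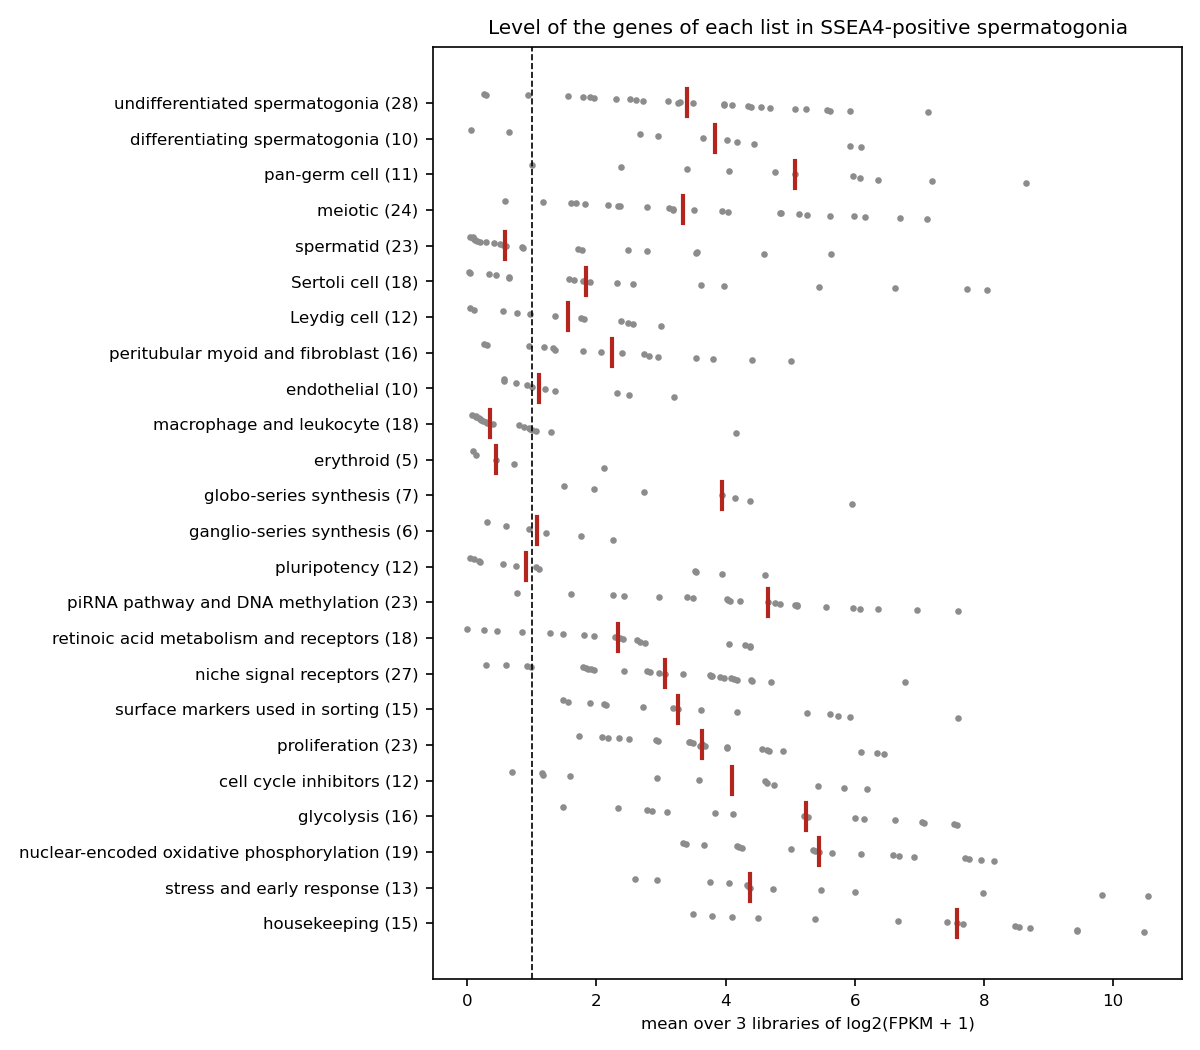
Each point is a gene, placed at its mean over 3 libraries of log2(FPKM + 1), by list with the number of measured genes in brackets; red bars are medians and the dashed line is 1 FPKM. The pan-germ cell median lies to the right of the medians of other testis cell lists, and the leukocyte, spermatid, erythroid and pluripotency medians lie left of the line.

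Receptors for signals of the stem cell niche were mostly above the level, 23 of 27, led by IL6ST at 109 ± 8.08 FPKM and NOTCH2 at 25 ± 2.05, while 2 lay below, with CSF1R at 0.227 ± 0.0271. All 15 measured surface markers used in cell sorting lay above 1 FPKM, with ITGB1 at 194 ± 17.1 and NCAM1 at 59.9 ± 5.28. Of 17 tested genes of retinoic acid metabolism and reception, 14 lay above and 2 below (3 when adjusted over the list alone, the only list where that adjustment changed a count), with RARA at 19.8 ± 3.06 and ALDH1A2 at 19.8 ± 2.24, and CYP26A1, which degrades retinoic acid, at 0.195 ± 0.0349.

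All 23 measured proliferation genes lay above 1 FPKM, with the replication factors MCM6 at 86.7 ± 5.51 FPKM and PCNA at 80.5 ± 4.10. Of 12 cell cycle inhibitors, 10 lay above, with RB1 at 72.6 ± 7.62 and CDKN1A at 56.7 ± 10.3. The proliferation list exceeded the inhibitors by 0.25 ± 0.06 in 3 of 3 libraries, but by medians it was lower, at -0.50. All 16 glycolysis genes and all 19 nuclear-encoded oxidative phosphorylation genes lay above the level, with GAPDH at 191 ± 10.03, PKM at 188 ± 38.1, COX4I1 at 286 ± 33.3 and ATP5PO at 248 ± 8.86. Glycolysis minus oxidative phosphorylation was -0.73 ± 0.15 on the log2 scale, higher in 0 of 3 libraries. The 13 stress and early response genes and the 15 housekeeping genes measured all lay above 1 FPKM, with HSPA8 at 905 ± 20.9 and EGR1 at 65.9 ± 21.

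The 13 mitochondrially encoded genes took 56.6% ± 3.45 (SD, n = 3) of the summed FPKM and the ribosomal protein genes 3.95% ± 0.042. Apart from these, the highest means were those of PTMA at 2287 ± 125 FPKM, PSIP1, a chromatin reader, at 2219 ± 217, H3F3A, a histone variant named H3-3A in the reference table, at 1772 ± 97.7, and YBX1 at 1679 ± 178. Next came HNRNPA2B1 at 1639.8 ± 39.9, HSP90AA1 at 1500.2 ± 216, TPT1 at 1453 ± 71.7, EEF1A1 at 1426 ± 51.8, HSP90AB1 at 1399 ± 129 and EIF3J at 1336 ± 99.7. Several of these, among them PTMA, H3F3A, TPT1 and EEF1A1, have near-identical copies in the genome, so their values are uncertain.

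Libraries S1 and S2 were closer to each other than either was to S3. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.997 for S1 and S2, 0.992 for S1 and S3, and 0.993 for S2 and S3, with Spearman's rho of 0.994, 0.988 and 0.989. Among 5961 genes with a mean of at least 10 FPKM, 8 differed over 2-fold on the scale of FPKM + 1 between S1 and S2, and 53 did so in each comparison with S3. Among the 10 genes with the largest SD of log2 values were PRM1, MT1X, a metallothionein, at 34.9, 22.7 and 4.73 FPKM in S1, S2 and S3, MX1, an interferon-induced GTPase, at 55.7, 52.9 and 11.12, FGF19 at 7.36, 6.66 and 31.7, S100A6 at 38.7, 33.3 and 9.14, and CRYAB at 20.03, 15.9 and 4.38. Whether S1 and S2 differ by more than sampling noise cannot be tested without counts.

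**Figure D3:**
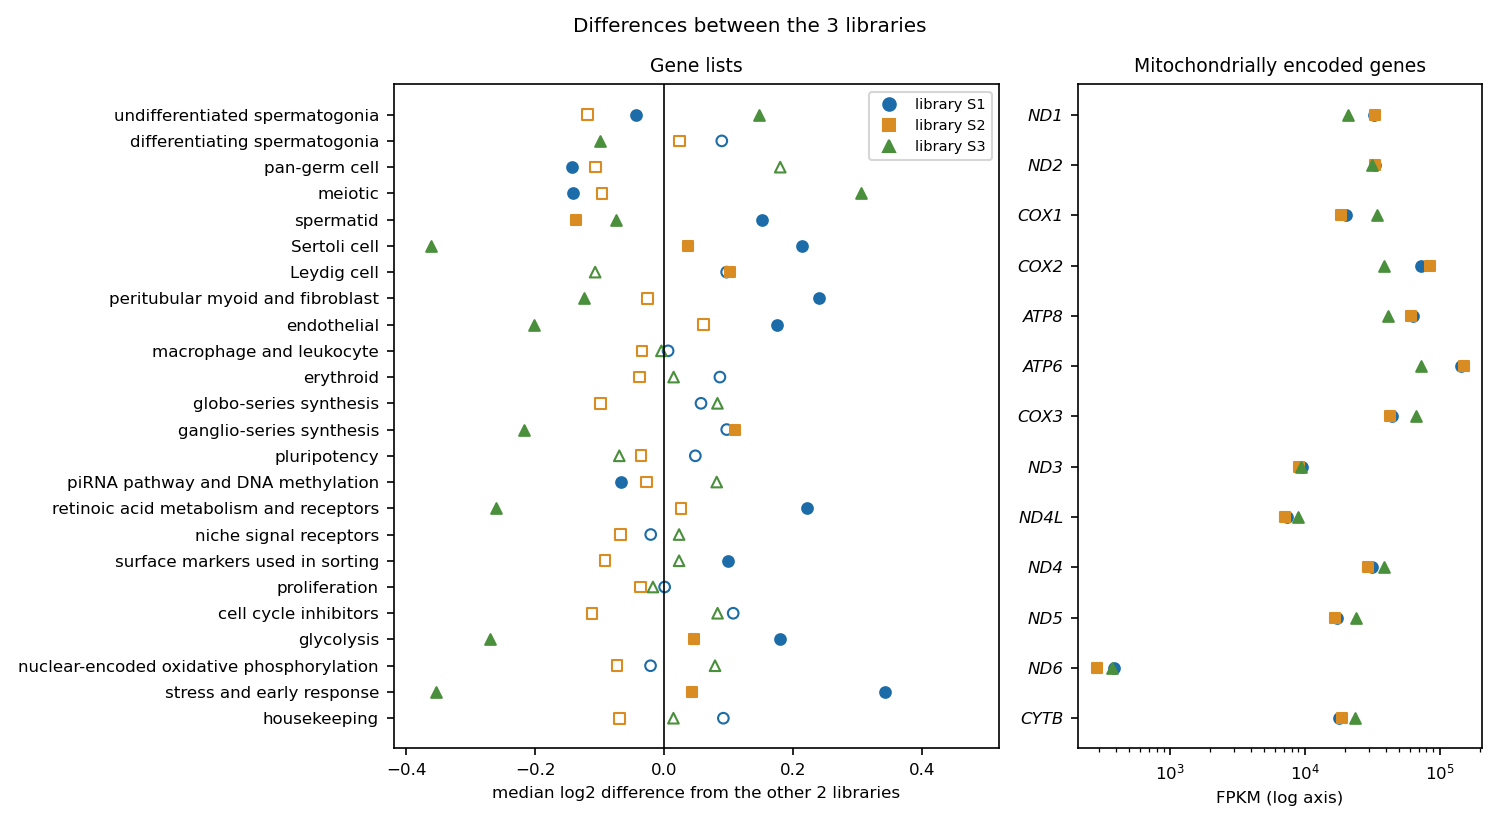
Left, the median log2 difference of each library from the mean of the other 2 for each list; filled symbols lie outside the central 95% of matched random lists. Right, FPKM (log axis) of the 13 mitochondrially encoded genes; ATP6 stands at 72494 FPKM in S3 and at 143612 in S1.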

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

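The rescaling of each library to 1000000 and the globo-series list without UGCG, B4GALT5 and B4GALT6 were chosen after the data were seen. No paired analysis was possible because the samples form 1 group. The depth of the libraries is unknown, so its effect on low values was not tested. Genes below 1 FPKM numbered 2924 with mitochondrial and ribosomal protein genes removed, where 959 calls had the opposite direction, because the rest were rescaled upwards, and 798 with a mean of at least 0.5 FPKM required, since fewer low genes were tested. At a level of 5 FPKM, 7632 genes lay above and 9130 below. Under the other settings both counts stayed within 1.5 times those reported. The difference between undifferentiated and differentiating lists was 0.17 with a pseudocount of 0.1 and 0.067 with mitochondrial and ribosomal protein genes removed, and ranged from -0.10 to 0.033 with each library left out. By medians, undifferentiated minus meiotic was 0.070 and proliferation minus inhibitors -0.50; the cause was not tested. The other 11 pair differences kept their direction in all settings run, with globo-series minus ganglio-series at 1.40 without those 3 genes. The mean Pearson r of 0.994 was 0.990 with a pseudocount of 0.1 and 0.991 with the filter, and ranged from 0.992 to 0.997 with each library left out. With mitochondrially encoded genes left out of the total, the 10 highest genes took 7.07%, the 100 highest 22.3% and ribosomal protein genes 9.14%. List levels moved by less than their SD in 24 of 24 lists under quantile normalization, but by more in 24 with mitochondrial and ribosomal protein genes removed, 20 after rescaling to 1000000, 16 with a pseudocount of 0.1 and 10 of 23 with the filter. At the level of 5 FPKM the log2 difference from the level was -0.62 for GFRA1, -1.02 for THY1, -0.46 for HBB, -0.63 for ST3GAL1, -1.09 for A4GALT, -0.32 for ST3GAL5 and -0.83 for ST8SIA5. With mitochondrial and ribosomal protein genes removed it turned to 0.92 for EOMES, 1.01 for TEX11, 0.34 for MEI1 and 0.66 for TET1, which then lay above, and to 0.43 for STRA8, not told apart. At the level of 0.5 FPKM it turned to 0.35 for EOMES, 0.41 for TEX11 and 0.19 for TET1, which lay above, and to 0.058 for STRA8 and 0.0034 for MEI1, not told apart. Calls also ended, with the direction kept, for LIN28A at -0.26 with those genes removed, TET1 at -0.11 after rescaling to 1000000, PRM1 with no filter, and PRM1, FGF19, ZBTB16, CYP11A1 and ST3GAL2 at the level of 5 FPKM.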

Other observations

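All tests of explanations below, and the comparison of lists between libraries, were chosen after the values were seen. Of 72 medians of a list in a library, which are not independent of each other, 29 lay outside the central 95% of matched random lists. Matched lists draw their genes independently, whereas members of a list may vary together between libraries. The percentiles, and the bootstrap intervals over genes, therefore give no chance level for a list. In S3 the median log2 difference from the other 2 libraries was -0.27 for glycolysis, with PKM at -0.45, and -0.26 for genes of retinoic acid metabolism and reception, with ALDH1A2 at -0.27 and RARA at -0.26. Meiotic genes moved the other way, at 0.31, with SMC1B at 0.43 and STAG3 at 0.40. The median of all genes with a mean of at least 1 FPKM was 0.05 in S3 as deposited and 0.17 after rescaling each library to 1000000. After that rescaling the values in S3 were -0.14 for glycolysis, -0.15 for retinoic acid and 0.44 for meiotic genes, or -0.31, -0.32 and 0.27 relative to all genes. None of these 3 lists changed direction in S3 under quantile normalization, removal of mitochondrial and ribosomal protein genes, or that rescaling.

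Sertoli cell genes were lower in S3, with CLU at -1.13 and VIM at -0.89, but WT1 stood at -0.04 and BEX1 at -0.12. Values minus the median of all genes with a mean of at least 1 FPKM argue against a scale factor of S3 alone. The Sertoli list, picked for the lowest percentile of the somatic lists, stood at -0.41, but 6 of its 18 members lay below 1 FPKM. Over its 12 members with such a mean it stood at -0.54, with a 95% bootstrap interval over genes from -1.03 to -0.13. By the same measure Leydig genes stood at -0.60, endothelial genes at -0.28 and peritubular genes at -0.16, with intervals that also left out 0. Fewer non-germ cells by the same factor cannot be told apart from other causes. Over members with a mean of at least 1 FPKM, the peritubular median, at -0.11, and the Leydig median, at -0.54, differed by 0.44. The 95% bootstrap interval over genes was from -0.16 to 0.81, so this test does not decide. Such members ranged in S3 from -1.34 to 0.14 in the Sertoli list and from -1.70 to 0.24 in the Leydig list. The leukocyte and erythroid lists, with 4 and 1 such members, were left out of this test. A weaker early response to handling may accompany the lower Sertoli genes. The stress and early response list stood at -0.35 in S3, with EGR1 at -0.81 but HSPA8 at 0.05. This does not show that the Sertoli genes were lower for that reason. No biological explanation was tested, as the labels give 1 group.

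Spermatid transcripts were highest in S1 for 17 of 23 genes, with PRM1 at 51 FPKM there against 1.53 in S2 and 11 in S3. Among members with a mean of at least 1 FPKM, the median in S1 was 0.97 for spermatid, 0.44 for Leydig, 0.40 for Sertoli, 0.34 for stress, 0.26 for peritubular and 0.23 for retinoic acid genes, so other lists were higher in S1 too. That mean includes S1, so a gene can pass through its value in S1 alone. By the same measure the median in S1 was -0.15 for meiotic, -0.15 for pan-germ cell and -0.05 for undifferentiated genes, but 0.09 for differentiating genes. The median over all 23 spermatid genes exceeded that of genes with a mean of at least 1 FPKM by 0.13, with a 95% bootstrap interval over genes from 0.07 to 0.51. These sets are unlike, as 14 of the 23 lay below 1 FPKM. Over the 9 spermatid genes with such a mean the excess was 0.95, with an interval from -0.03 to 1.83. These intervals therefore do not decide about a scale factor of S1. Over all 23 genes the S1 median lay above 100% of 10000 random lists matched in expression, which a factor common to all genes would not by itself produce. A trace of RNA from haploid germ cells in S1, in cells sorted for SSEA4, cannot be told apart from other causes, because the list median of 0.15 above the other 2 libraries is the pattern itself. No biological explanation was tested.

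The 13 mitochondrially encoded genes split in S3, with ATP6 at -1.02 and COX2 at -1.03 but COX1 at 0.81 and COX3 at 0.61. A change in the amount of mitochondrial RNA by a single factor is argued against by their span of 1.84 on the log2 scale. Coding length could be involved and cannot be told apart from chance with 13 genes, which are not independent replicates, at a Spearman's rho of 0.53 across genes (permutation test, two-sided, p = 0.063) and a Pearson's r of 0.47. No biological explanation was tested.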
